A study of Mus musculus with 12 samples.

How the data were processed

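RNA of adrenal glands from transgenic mice carrying extra copies of Ftz-F1 (Nr5a1, which encodes the nuclear receptor SF-1) was compared with RNA of a wild-type littermate of the same sex and age on 2-colour arrays. Each of 6 transgenic and wild-type pairs was hybridized on 2 arrays with the dyes exchanged, which gives 12 arrays. The pairs are named here by the number of the transgenic mouse in the labels. Pairs 11, 13 and 15 were 10 days old with 1 transgene copy, and pairs 1, 3 and 5 were 4 months old with 2 copies. Pairs 15 and 5 were female and the other 4 male. Age and copy number change together, so neither can be separated from the other. By their descriptions, all arrays with the transgenic sample in Cy3 form batch A and all with it in Cy5 batch B. A difference between the dye orientations can therefore not be separated from one between these batches.

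The deposited values are log2 ratios of the 2 channels for 25344 spots per array. On the 6 arrays with the transgenic sample in Cy3, stored at full precision, 2 raised to each value was a ratio of whole numbers no larger than 65535, for 100% of spots within a relative tolerance of 1e-13. With base e or base 10 the share was at most 0.579% and 0.746%. The authors' normalization, scanner, image analysis and background subtraction are not given in the sources used here. The deposited values were not centred: array medians ran from -0.68 to -0.22 on arrays with the transgenic sample in Cy3 and from 0.74 to 1.50 on those with it in Cy5. They also followed spot signal, with medians of the dimmest of 12 signal bins from -1.17 to -0.45 and from 1.27 to 2.21, and medians of the brightest bins from -0.19 to 0.54 and from -0.11 to 0.41. Between 4.31% and 6.59% of spots were empty per array, 600 probes were empty on all arrays and 22438 had a value on all 12. Signal over background is unknown, and the number of arrays limits the precision.

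A pair of steps departed from the plan fixed before the data were examined, which had taken the values as normalized and had left the columns unturned only where the arrays of a dye swap correlated above 0 over all probes. First, each array was corrected by a loess curve (span 0.3) of the ratio on the signal of the probe, since the values were not normalized. The signal of a probe was the 75th percentile over the 6 full-precision arrays of the geometric mean of the whole numbers recovered for its spot, up to a factor common to both, and it was recovered for 24636 probes. Spots with a signal of at least 32768, the upper part of the range of a 16-bit scanner, are described as near the limit of the scanner. Second, the columns were not turned. The correlation of the 2 arrays of a pair as deposited was -0.50 to -0.10, but arrays of different pairs with opposite dyes also gave -0.62 to -0.25, so this value follows the dye. After the mean of the arrays of the same dye orientation was taken off, the 2 arrays of a pair correlated at 0.23 to 0.66, against -0.28 to 0.12 for the 30 combinations of different pairs. The columns therefore already ran the same way for each pair. Whether they hold transgenic over wild type or the inverse is not given in the sources used here, and signs are reported as deposited.

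Probes were assigned to genes with the platform's annotation table. Of its 21112 probes with a gene, 21082 had a single gene and 30 several, and 4232 probes had none. Symbols were checked against the mouse RefSeq annotation. Probes of the same gene were averaged, and the 2 arrays of a pair were averaged to 1 value where both were measured. A feature was tested if at least 2 of the 3 pairs of each group had a value, which left 21512 features, of which 17881 were named genes.

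The 6 pair values were fitted in limma 3.58.1 under R 4.3.3 with a mean per group, and moderated statistics used 4 residual and 3.85 prior degrees of freedom. Tested were the 10-day mean, the 4-month mean, the mean over all 6 pairs, the 4-month minus the 10-day mean and, with a sex term added, the female minus male difference. All tests were two-sided, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. The same pair values were also tested with an ordinary linear model without moderation. Data were simulated with the arrays' dye trend and probe dye effects and with normal noise of the estimated spread, drawn independently by gene. This procedure recovered 86.6% of genes given a log2 change of 1 in either group of these data. It recovered 95.5% over all 6 pairs and 35.8% for the difference between the groups. Over all 6 pairs 11.5% of the calls on simulated data were false, which is above the nominal 5%. Each share came from 1 simulated data set without correlated genes or outlying pairs, so it may not hold for the real arrays. Each set held 67 genes with a log2 change of 0.5, 67 with 1 and 66 with 2. So many true changes ease the adjusted threshold. Where fewer genes change, a smaller share could pass, so a count of 0 does not exclude changes of 1.

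Before the data were examined, the comparisons, the 27 gene lists, the alternatives and the rule for named genes were fixed. The rule took up to 10 called genes in each direction for each group and for all 6 pairs, with the same sign on every array, and up to 5 in each direction for the differences. Where no gene passed, the 5 in each direction with the smallest p were named as not passing. Nr5a1, its neighbour Nr6a1 and Vnn1 were always named, and called members of each list or up to 2 with the smallest p were added. Clone names were passed over. Other genes, named where their values stand out in 1 pair, were chosen after their values were seen. The lists were steroidogenesis, cortical transcription factors and zonation signals, gonadal-type genes, cholesterol synthesis and uptake, cell cycle and DNA replication, imprinted and insulin-like growth factor genes, steroid and thyroid hormone response, glutathione and oxidative stress, oxidative phosphorylation, ribosomal proteins, interferon response, immediate early and stress genes, neighbours of Nr5a1, and Y-linked genes with Xist. Lists of cell type markers were X-zone, adrenal medulla, Schwann and glial cells, macrophages, lymphocytes and antigen presentation, endothelial cells, capsule with fibroblasts and smooth muscle, adipocytes, erythroid cells, kidney tubule cells, hepatocytes, exocrine pancreas and skeletal muscle.

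Lists were tested with camera at a preset correlation of 0.01, adjusted over the 27 lists of a comparison. Camera with an estimated correlation and the rotation test fry were alternatives. The medians of each list in the 6 pairs were also tested by an exact two-sided sign-flip test, whose smallest possible p is 0.0312 with 6 pairs and 0.25 with 3. The alternatives changed the dye orientation used, the normalization, the filter, the level (gene or probe), the model, the threshold and the pairs included, and others were added after the data were seen. Tables were prepared with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and plots with matplotlib 3.10.9. No array was left out.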

Results

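Adrenal gland transcripts of 6 transgenic mice with extra copies of Ftz-F1 (Nr5a1) were measured against those of their wild-type littermates on 12 arrays of 25344 spots. Nr5a1 encodes SF-1, a nuclear receptor required for adrenal and gonadal development. There were 3 pairs of 10-day-old mice with 1 transgene copy and 3 pairs of 4-month-old mice with 2 copies, with 2 dye-exchanged arrays per pair, and each group held 1 female pair. Between 4.31% and 6.59% of spots were empty on an array, and 21512 features were tested, of which 17881 were named genes. All values are log2 ratios after correction of the dye trend, in the direction in which they were deposited. A positive ratio stands for a higher level in the transgenic mouse if the ratio is transgenic over wild type, and for a lower level if it is the inverse, which is not given in the sources used here.

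Over all 6 pairs, which ask for genes regulated by the transgene whatever the age, 11 genes had a positive ratio and 1 a negative ratio that passed. Of the positive genes, 3 belong to the chromaffin cells of the adrenal medulla. They are Gal, which encodes the neuropeptide galanin, at 1.20 (SE 0.12, 6 pairs), Scg5, a secretory granule protein, at 0.79 (SE 0.08, 6 pairs), and Pcsk1, a prohormone convertase, at 0.67 (SE 0.08, 6 pairs). Gja1, which encodes a gap junction connexin, was the negative gene, at -1.02 (SE 0.09, 6 pairs).

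The other 8 positive genes lay between 0.63 and 0.90. They were Samt3 at 0.90 (SE 0.07), Slc35d3 at 0.89 (SE 0.09), the estrogen-binding receptor gene Gper1 at 0.85 (SE 0.09), the stathmin gene Stmn3 at 0.84 (SE 0.09), the neuropeptide Y receptor gene Npy2r at 0.77 (SE 0.07), the sarcalumenin gene Srl at 0.76 (SE 0.08), Nap1l5 at 0.70 (SE 0.08) and the potassium channel gene Kcnc4 at 0.63 (SE 0.07). All 12 had the same sign in 6 of 6 pairs, and all but Gper1 had it on all 12 arrays. Adjusted p-values in limma ran from 0.0292 for Samt3 and Gja1 to 0.0484 for Stmn3, Nap1l5, Pcsk1 and Kcnc4. At an unadjusted p under 0.05 there were 3236 features, 1625 positive and 1611 negative, against 1076 expected by chance. The ordinary linear model called 1 gene, Olfr849, at 0.35 with adjusted p = 0.0402, and none of the 12; this gene was named after its value was seen. Leaving out a single pair gave 4 genes without pair 11 (Col5a3, Gal, Gja1 and Top1mt, named after their values were seen), 0 without pair 13, 15, 1 or 3, and 13 without pair 5, and no gene passed when arrays were centred on their median or when sex was added to the model.

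**Figure D1:**
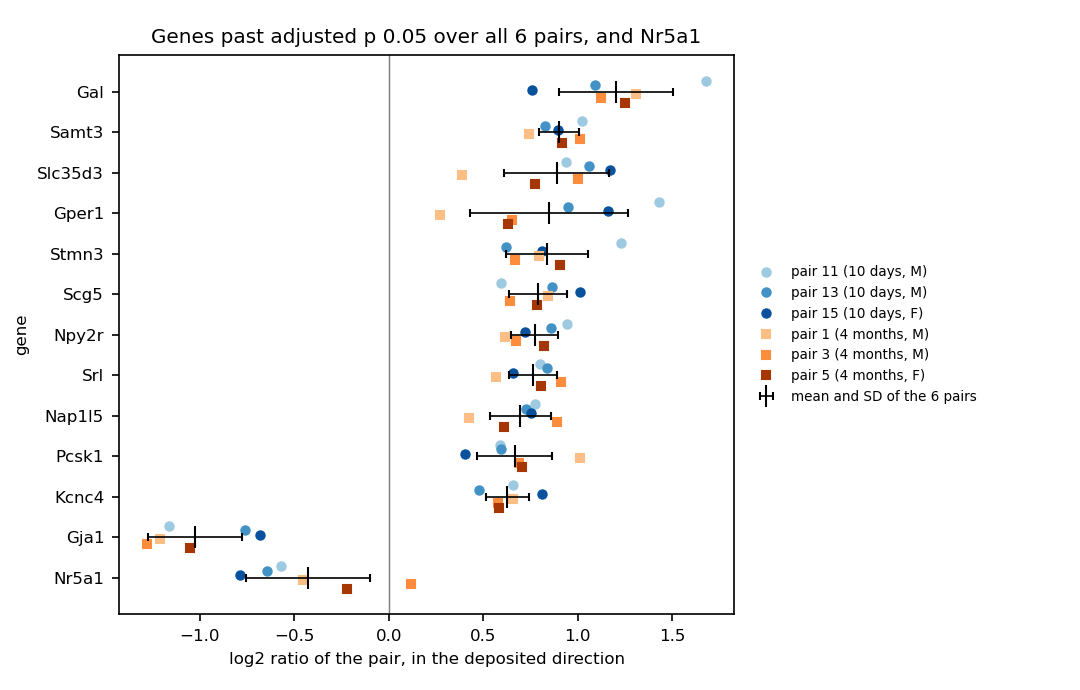
Log2 ratios (horizontal axis, deposited direction) of the 12 genes past the threshold over all 6 pairs and of Nr5a1, with a point for each pair, circles for 10 days and squares for 4 months, and the mean and SD of the 6 pairs. Gal has a mean of 1.20, Gja1 of -1.02, and Nr5a1 lies from -0.79 to 0.12.

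As a group, the chromaffin cell genes had positive ratios in both ages. Of 28 measured members, 25 were positive over all 6 pairs, with a median of 0.29, and 3 passed over all genes, or 13 when adjusted over the list alone, and the median was 0.47 without pair 11. The median of the list was positive in 6 of 6 pairs, from 0.14 in pair 11 to 0.65 in pair 15, with a mean of 0.39 ± 0.20 (SD, n = 6, exact sign-flip p = 0.0312, the smallest possible, 0.281 adjusted over 27 lists). Pnmt, which encodes the adrenaline-forming enzyme, was at 1.15 ± 0.44 (SD, n = 6) and Npy at 1.13 ± 0.53 (SD, n = 6), neither past the threshold over all genes. Th, which encodes the rate-limiting enzyme of catecholamine synthesis, was at 0.79, and Dbh at 0.23, Chgb at -0.03 and Chga at -0.17. The Chga spots were near the limit of the scanner. Camera gave adjusted p = 7.88e-12 with the preset correlation, and adjusted p = 0.425 with an estimated correlation (unadjusted p = 0.016). The rotation test fry, which asks whether the genes of a list move one way, gave adjusted p = 0.0434.

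3 other lists passed over all 6 pairs with the preset correlation. The interferon response genes had a median of -0.30, with 21 of 26 members negative and adjusted p = 3.83e-05, and adjusted p = 0.83 with an estimated correlation. The lymphocyte and antigen presentation genes had a median of -0.41, with 20 of 22 negative and adjusted p = 4.87e-04, and adjusted p = 0.83 with an estimated correlation. The hepatocyte genes had a median of 0.35, with 13 of 15 positive and adjusted p = 0.0154, and adjusted p = 0.83 with an estimated correlation. Adjusted over the list alone, 5 interferon genes and 2 lymphocyte genes passed with negative ratios and 0 hepatocyte genes, of which limma had 3 at an unadjusted p under 0.05. Fry also called the Y-linked genes with Xist, with adjusted p = 0.0434 and a median of 0.07 over 7 members, while camera gave adjusted p = 0.352 with the preset and 0.83 with an estimated correlation. Of this list, Uty was positive in 6 of 6 pairs, the female pairs 15 (0.08) and 5 (0.36) among them. Female mice have no Y chromosome, so the sign of Uty in those pairs does not come from its transcript. The hepatocyte median was 1.42 in pair 11 and between -0.01 and 0.26 in the other pairs, and the list did not pass without pair 11 (median 0.07, adjusted p = 0.196) or without pair 3 (0.30, adjusted p = 0.139). The lymphocyte median was -1.87 in pair 3 and between -0.15 and 0.04 in the other pairs, and the list did not pass without pair 3 (median -0.04, adjusted p = 0.289), where the interferon list was at -0.16 (adjusted p = 0.00871). Without pairs 11, 15 and 3 together, the hepatocyte median was 0.01 (adjusted p = 0.481) and the lymphocyte median -0.08 (adjusted p = 0.174), while the interferon list was at -0.23 (adjusted p = 4.54e-05) and the chromaffin list at 0.26 (adjusted p = 5.13e-09). This fit took a single mean over pair 13 at 10 days and pairs 1 and 5 at 4 months. It thus weighs the 4-month pairs more than the mean over all 6 pairs does. Lists that passed in it but not over all 6 pairs were ribosomal proteins (-0.18, camera adjusted p = 0.00258), macrophages (-0.229, 0.0155) and capsule and fibroblasts (-0.205, 0.0376). Each of these also passed at 4 months with all pairs, with camera adjusted p = 5.06e-04, 2.26e-05 and 0.0264. Without pair 3, 2 lists passed, without pair 15, 8, and without pair 1, 7.

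At 10 days with 1 copy, no gene passed, and the genes with the smallest p are given as values. Hdc, which encodes the histamine-forming enzyme, was at -1.49 ± 0.41 (SD, n = 3), the mitochondrial topoisomerase gene Top1mt at -1.40 ± 0.55 (SD, n = 3), Tmem176b, whose spots were near the limit of the scanner, at -0.94 ± 0.12 (SD, n = 3), Tbrg1 at -0.93 ± 0.06 (SD, n = 3) and Gja1 at -0.87 ± 0.26 (SD, n = 3). On the positive side stood Gper1 at 1.18, Slc35d3 at 1.06, Samt3 at 0.92, Npy2r at 0.84 and Scg5 at 0.82. All 10 had the same sign in 3 of 3 pairs and an adjusted p of 0.157 in limma. The count was 0 in limma and 0 in the ordinary model, with 1797 features at an unadjusted p under 0.05, 919 positive and 878 negative, against 1076 expected by chance. Without pair 11, limma called 1 gene, Top1mt, at -1.71 with adjusted p = 0.0359.

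The chromaffin list was positive at 10 days as well, with 23 of 28 members positive, a median of 0.29 and 7 members past the threshold when adjusted over the list alone, against 0 over all genes in limma. Camera gave adjusted p = 1.61e-10, and adjusted p = 0.516 with an estimated correlation. The hepatocyte list had 13 of 15 members positive and a median of 0.51, with adjusted p = 2.3e-04, and adjusted p = 0.889 with an estimated correlation. Its median was 1.42 in pair 11 and 0.04 and 0.07 in pairs 13 and 15, and in pair 11 Alb, the albumin gene, was at 6.72 and Ahsg at 5.56. Without pair 11 the hepatocyte list did not pass (median 0.03, adjusted p = 0.335), and without pair 13 it was at 0.79 (adjusted p = 2.77e-07). The cholesterol synthesis and uptake list had 17 of 22 members negative and a median of -0.15, with adjusted p = 0.0418, and adjusted p = 0.889 with an estimated correlation. Its members Lss, a sterol-forming cyclase gene, and Fdps were at -0.64 ± 0.38 and -0.41 ± 0.59 (SD, n = 3). The Lss value came from arrays with the transgenic sample in Cy5, from -1.98 to -0.95, while those with it in Cy3 lay from -0.09 to 0.41. 3 lists passed in all, 6 without pair 13 and 5 without pair 15, and without pair 15 the cholesterol list did not pass (median -0.05, adjusted p = 0.87), while without pair 13 it was at -0.26 (adjusted p = 6.71e-04).

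At 4 months with 2 copies, no gene passed. Chst8, a sulfotransferase gene, was at 1.15 ± 0.07 (SD, n = 3), Gal at 1.22 ± 0.10 (SD, n = 3), Hs3st2, a heparan sulfate sulfotransferase gene, at 0.99 ± 0.20 (SD, n = 3), Samt3 at 0.89 and Pcsk1 at 0.80. On the negative side stood Gja1 at -1.18 ± 0.12 (SD, n = 3), Irf8, a transcription factor gene of myeloid cells, at -1.11 ± 0.45 (SD, n = 3), Epb41l3 at -0.98, Bcl2l12 at -0.88 and the glutathione transferase gene Mgst1 at -0.80. All 10 had the same sign in 3 of 3 pairs, with adjusted p-values from 0.136 to 0.208 in limma. The count was 0 in limma and 0 in the ordinary model, with 2655 features at an unadjusted p under 0.05, 1311 positive and 1344 negative, against 1076 expected by chance. Without pair 5, limma called 2 features, Atg101 at 2.24 with adjusted p = 0.0183 and a probe without a gene at -2.48, both singled out after their values were seen.

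Genes of immune cells had negative ratios at 4 months. In the interferon response list 25 of 26 members were negative, with a median of -0.49 (14 past the threshold when adjusted over the list alone, 0 over all genes), for example Irf7 at -1.27 ± 0.61 and Gbp3 at -0.68 ± 0.31 (SD, n = 3). In the lymphocyte and antigen presentation list 21 of 22 were negative, with a median of -0.73 (5 adjusted over the list alone), among them H2-Ab1 at -1.72 ± 0.95 and H2-Eb1 at -0.94 ± 0.52 (SD, n = 3). In the macrophage list 20 of 25 were negative, with a median of -0.60 (12 negative and 1 positive adjusted over the list alone), among them Aif1 at -1.84 ± 1.04 and the complement gene C1qc at -1.24 ± 0.40 (SD, n = 3). Camera gave adjusted p-values of 8.86e-10, 7.6e-08 and 2.26e-05, and each was at adjusted p = 0.677 with an estimated correlation. Pair 3 had the lowest median in all 3 lists, -0.76, -1.87 and -1.20, against -0.40, -0.08 and -0.07 in pair 1 and -0.14, -0.15 and -0.47 in pair 5. In pair 3 the B-cell receptor genes Cd79b and Cd79a were at -5.18 and -4.18 and the macrophage receptor gene Marco at -6.25. Without pair 3 the lymphocyte list did not pass (median -0.13, adjusted p = 0.111), and the interferon and macrophage medians were -0.25 and -0.35 (adjusted p = 4.68e-05 and 0.00667).

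The chromaffin list had 24 of 28 members positive at 4 months, with a median of 0.42, 10 past the threshold when adjusted over the list alone, camera adjusted p = 1.11e-08, and adjusted p = 0.677 with an estimated correlation. Ribosomal protein genes had 34 of 41 members negative and a median of -0.25, with adjusted p = 5.06e-04, and adjusted p = 0.677 with an estimated correlation, for example Rps29 at -0.92 ± 0.55 and Rpl32 at -0.36 ± 0.08 (SD, n = 3). Of the 41 members 9, Rpl32 among them, had spots near the limit of the scanner, and of the other 32, with a median of -0.28, 27 were negative. Genes of the capsule, fibroblasts and smooth muscle had 22 of 25 members negative and a median of -0.17, with adjusted p = 0.0264, and adjusted p = 0.677 with an estimated correlation, for example Sparc at -0.42 ± 0.16 and Col6a1 at -0.36 ± 0.21 (SD, n = 3). 6 lists passed in all and 3 without pair 3, where the ribosomal protein list (median -0.14) and the capsule list (-0.20) were at adjusted p = 0.111. Without pair 1 the capsule list was at -0.14 (adjusted p = 0.143), and without pair 5 at -0.26 (adjusted p = 0.0274).

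**Figure D2:**
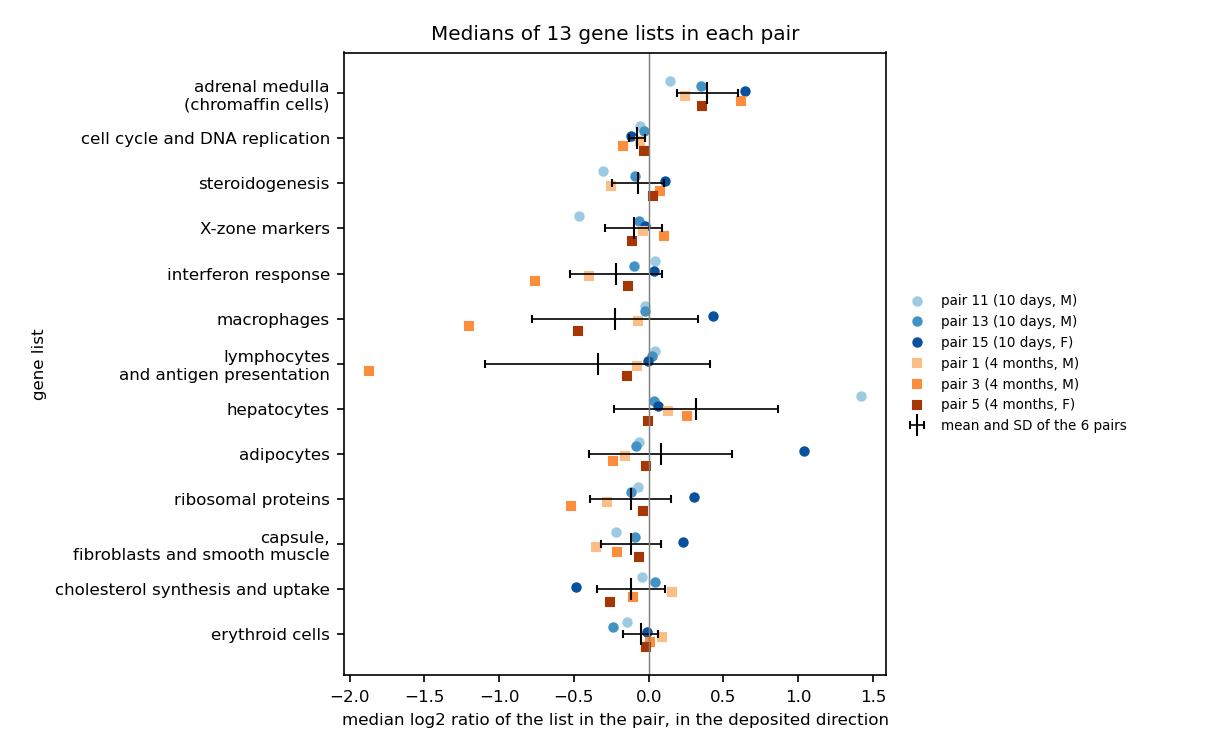
Median log2 ratio (horizontal axis, deposited direction) of 13 gene lists in each pair, circles for 10 days and squares for 4 months, with the mean and SD of the 6 pairs. The chromaffin list is positive in 6 of 6 pairs, while single pairs stand apart for hepatocytes (pair 11, 1.42), adipocytes (pair 15, 1.04) and lymphocytes (pair 3, -1.87).

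The difference between the groups asks whether the change depends on age and copy number, which cannot be separated. No gene passed. Slc38a5, an amino acid transporter gene, was at -0.72 ± 0.14 at 10 days and 0.56 ± 0.23 at 4 months (SD, n = 3), Mgst3 at -0.64 ± 0.30 and 0.71 ± 0.20, Odc1, which encodes the first enzyme of polyamine synthesis, at -0.64 ± 0.29 and 0.93 ± 0.60, and Zfand1 at -0.45 ± 0.10 and 0.49 ± 0.22. Hdc was at -1.49 and -0.11. In the other direction, the class I antigen presentation gene H2-K1 was at 0.47 ± 0.20 and -1.49 ± 0.86, Lilrb4a at 0.46 and -0.63, Sulf1 at 0.15 and -0.73, Epb41l3 at -0.13 and -0.98, and Slfn8 at -0.00 and -0.69. The 10-day H2-K1 value averages arrays of opposite sign in every pair. They lay from 1.57 to 2.02 with the transgenic sample in Cy5 and from -1.27 to -0.28 with it in Cy3. At 4 months H2-K1 was negative on every array. The smallest adjusted p in limma was 0.933, with 988 features at an unadjusted p under 0.05, against 1076 expected by chance, and 0 genes in the ordinary model.

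7 lists differed between the groups with the preset correlation, and 0 with an estimated correlation, where the lowest adjusted p was 0.683. The 4-month minus 10-day medians were -0.43 for interferon response (adjusted p = 3.78e-09), -0.66 for macrophages (1.32e-07), -0.69 for lymphocytes (2.71e-07), -0.30 for ribosomal proteins (6.82e-06), -0.58 for adipocytes (0.00238), 0.15 for erythroid cells (0.0232) and -0.40 for hepatocytes (0.0267). Adjusted p-values with an estimated correlation were 0.683 for interferon, macrophages, ribosomal proteins, adipocytes and erythroid cells, 0.773 for lymphocytes and 0.844 for hepatocytes. Adjusted over the list alone, 8 macrophage genes, 1 adipocyte gene and 1 hepatocyte gene passed. The adipocyte median was 1.04 in pair 15 and the hepatocyte median 1.42 in pair 11, and without pair 11 the hepatocyte difference was 0.13 (adjusted p = 0.665). Calls of the difference also ended for adipocytes without pair 15 (-0.08, adjusted p = 0.247), ribosomal proteins without pair 15 (-0.18, adjusted p = 0.0575) and lymphocytes without pair 3 (-0.18, adjusted p = 0.111). They ended for erythroid cells without pair 11 (0.14, adjusted p = 0.114), 13 (0.07, 0.269) or 3 (0.17, 0.111), and for hepatocytes without pair 1 (-0.38, 0.0676) or 5 (-0.25, 0.335). Lists still called moved to -0.23 for interferon (2.87e-04) and -0.36 for macrophages (4.25e-05) without pair 3, to -1.04 for lymphocytes without pair 1 (2.55e-12) and -1.03 without pair 5 (2.58e-08), to -0.87 for adipocytes without pair 11 (2.22e-04) and to 0.31 for erythroid cells without pair 15 (1.09e-04). In pair 15 the adipokine gene Adipoq was at 5.13 and the fatty acid carrier gene Fabp4 at 2.74. Of the erythroid list, the globin regulator gene Klf1 was at -0.71 ± 0.61 at 10 days and 0.21 ± 0.35 at 4 months (SD, n = 3).

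No gene differed between the sexes in limma among 21503 features, with 2 female and 4 male pairs and a smallest adjusted p of 0.746. At an unadjusted p under 0.05 there were 1237 features, 735 with a positive and 502 with a negative female minus male difference of the ratio, against 1075 expected by chance, and the ordinary model called 1 gene, Mthfd1, at -0.35 with adjusted p = 0.0365, named after its value was seen. Hand2, a transcription factor gene of sympathoadrenal cells, was at 0.74 and 1.24 in the female pairs and between -0.57 and 0.08 in the male pairs (female minus male 1.23, SE 0.16). Smpdl3b was at -1.34 and -2.01 in the female pairs and between -0.03 and 0.17 in the male pairs, and Rps19 at 1.82 and 0.18 in the female pairs and between -1.22 and -0.21 in the male pairs. Rps19 was at 1.65 (SE 0.23), Rps3a1 at 1.34, Ikbke at 1.00 and Slc29a1 at 0.97, and Smpdl3b at -1.73 (SE 0.20), Abra at -1.63, Mgp at -1.61, Abhd14b at -1.24 and Sc5d, a sterol desaturase gene, at -1.12, all female minus male. Abra was not measured in pair 15, so its value rests on a single female pair, pair 5, at -1.54. Without pair 15 the female arm held pair 5 alone, which is assumed to vary like the other pairs, and 3 features were called, Pik3c2g at -5.91 (pair 5 itself at -5.77), Sdr42e1 at 5.57 and a probe without a gene at 3.33, and without pair 3, 1, Adh7 at -3.03, all named after their values were seen.

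Nr5a1, the gene of the transgene, had a negative ratio at 10 days in 3 of 3 pairs, at -0.67 ± 0.11 (SD, n = 3), and in 2 of 3 pairs at 4 months, at -0.18 ± 0.29 (SD, n = 3), or -0.05 without pair 1 and -0.34 without pair 3. Neither passed, with limma adjusted p-values of 0.337 and 0.573. The 10-day means were -0.70 on arrays with the transgenic sample in Cy5 and -0.63 with it in Cy3, and the 4-month means -0.50 and 0.13. Whether the probe detects the transcript of the transgene is not given in the sources used here. Its genomic neighbours Nr6a1, at -0.16 (SE 0.07), and Psmb7, a proteasome subunit gene, at -0.51 (SE 0.08), were negative in 6 of 6 pairs, with adjusted p-values of 0.315 and 0.0761 in limma. Another neighbour, Nek6, was at -0.25. The list of 12 measured neighbours had a median of -0.07 over all 6 pairs (camera adjusted p = 0.183). Vnn1, which encodes pantetheinase, was negative in 5 of 6 pairs, from -2.89 in pair 13 to -1.02 in pair 1, and was 1.68 in pair 15, with a mean of -1.22 (SE 0.50, limma adjusted p = 0.315), or -0.70 without pair 13 and -1.84 without pair 15.

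The lists closest to adrenal function did not pass over all 6 pairs. Of 20 measured steroidogenesis genes 14 were negative, with a median of -0.08 and camera adjusted p = 0.274, among them Cyb5a, a steroidogenic cofactor, at -0.54 (SE 0.12) and Dhrs3 at -0.46 (SE 0.09). The 8 X-zone markers had a median of -0.28 (adjusted p = 0.352), with Nr0b1, which encodes a repressor of SF-1, at -0.40 (SE 0.12) and Cyp2f2 at -1.04 (SE 0.47), or -0.48 without pair 15. In pairs 1 and 3 Nr0b1 was at -1.89 and -1.10 with the transgenic sample in Cy3, but at 0.06 and 0.02 with it in Cy5. Cortical transcription factors and zonation signals had a median of -0.04 (adjusted p = 0.817), with Nr2f1 at 0.51, and a positive direction in camera. Gonadal-type genes had a median of -0.03 (adjusted p = 0.683), with Amhr2 at -0.39 and Fshr at 0.29. Cholesterol synthesis and uptake had a median of -0.08 (adjusted p = 0.114), with Fdps at -0.62 and Lss at -0.32.

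Of 47 cell cycle and DNA replication genes 34 were negative over all 6 pairs, with a median of -0.08 (camera adjusted p = 0.114). Their medians per pair were negative in 6 of 6, from -0.17 to -0.03 (exact sign-flip p = 0.0312, the smallest possible, 0.281 adjusted over 27 lists). By dye orientation, the cell cycle median was positive in pairs 1 and 5 with the transgenic sample in Cy5 and in pair 13 with it in Cy3. Mcm3, a replication helicase gene, was at -0.71 (mean of 5 pairs) and Top2a at -0.35. The skeletal muscle list was positive in 6 of 6 pairs, from 0.01 to 0.08, with the same exact sign-flip p = 0.0312 and 0.281 adjusted, and camera adjusted p = 0.343, with Myl1 at 0.78 and Ckm at 0.32. This sign did not hold by dye orientation. The muscle median was negative in pairs 11, 13 and 5 with the transgenic sample in Cy5, and in pairs 15, 3 and 5 with it in Cy3.

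The remaining lists did not pass over all 6 pairs. Their camera adjusted p-values were 0.98 for glutathione and oxidative stress (median -0.00), with Mgst1 at -0.54 and Gsta4 at 0.64, and 0.274 for oxidative phosphorylation (median 0.00), with Ndufa4 at 0.59 and Cyc1 at -0.26. They were 0.781 for imprinted and insulin-like growth factor genes (median 0.02), with Dlk1 at 0.48 and Phlda2 at -0.21, and 0.683 for steroid and thyroid hormone response (median -0.00), with Pdk4 at 0.63 and Thrsp at -0.15. Immediate early and stress genes gave 0.80 (median -0.07), with Hspa8 at 0.46 (its spots near the limit of the scanner) and Junb at -0.50, and ribosomal proteins 0.274 (median -0.08). Of cell type markers, the adjusted p was 0.0718 for macrophages (median -0.26), 0.131 for capsule and fibroblasts (-0.12), 0.352 for endothelial cells (-0.06), with Egfl7 at -0.44 and Emcn at -0.13, and 0.463 for erythroid cells (-0.08), with Ermap at -0.12. It was 0.683 for exocrine pancreas (0.07), with Amy2 at -0.21 and Prss2 at -0.23, 0.781 for Schwann and glial cells (-0.14), with S100b at 0.27 and Sox10 at -0.14, 0.813 for kidney tubule cells (0.00), with Napsa at -0.60 and Slc34a1 at 0.20, and 0.846 for adipocytes (-0.02), with Fabp4 at 0.68 and Lpl at -0.40. The Y-linked genes with Xist gave 0.352 (0.07), with Uty at 0.34 and Zfy1 at 0.17, and in the hepatocyte list Ttr was at 0.58 and Cyp2e1 at -0.13. Zfy1 lay from 0.02 to 1.42 on arrays with the transgenic sample in Cy5 and from -0.53 to 0.28 with it in Cy3. Egfl7 lay from -1.10 to -0.47 with the transgenic sample in Cy5 and from -0.42 to 0.435 with it in Cy3. The sign of the median was not that of the mean for adipocytes (mean 0.08), exocrine pancreas (-0.01), kidney tubule cells (-0.04) and steroid and thyroid hormone response (0.04). Camera's direction was negative for kidney tubule cells and positive for the other lists of these.

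The genes given above over all 6 pairs for these remaining lists and for hepatocytes were all short of the threshold over all genes. Of them, 13 moved by over 1.5 times when a single pair was left out. Klf1 and Rps29, given above by group only, also moved by over 1.5 times. Without pair 11, Hspa8 was at 0.23, Junb at -0.32, Lpl at -0.12, Thrsp at -0.10, Ttr at 0.37 and Zfy1 at 0.06. Without pair 13, Cyp2e1 was at -0.07, Hspa8 at 0.71, Sox10 at -0.07 and Thrsp at -0.09. Without pair 15, Amy2 was at -0.12, Fabp4 at 0.34, Lpl at -0.69, Pdk4 at 0.40, Slc34a1 at 0.12 and Thrsp at -0.27. Slc34a1 was at 0.13 without pair 1, Hspa8 at 0.29 and Napsa at -0.25 without pair 3, and Amy2 at -0.05 and Thrsp at -0.09 without pair 5.

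The changes at 10 days and 4 months were compared across genes, which are not independent replicates. Across 21512 features Pearson's r was 0.28 and Spearman's rho 0.29. At an unadjusted p under 0.05 in both groups there were 609 features, against 222 expected by chance, and 580 of them had the same sign. The 222 takes the groups as independent. A dye effect of single probes left after averaging would be shared by both groups, and its part in the 609 was not tested. When the 10-day arrays with the transgenic sample in Cy5 were set against the 4-month arrays with it in Cy3, r was -0.33. For the inverse r was -0.20, while arrays of the same dye orientation gave 0.58 and 0.45. The sign of r thus followed the dye orientation of the arrays compared, or the batch of descriptions that changes with it. Without pair 11, r was 0.18.

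The 2 arrays of a pair, across probes, correlated at 0.31 in pair 11, -0.01 in pair 13, 0.18 in pair 15, -0.02 in pair 1, 0.41 in pair 3 and 0.12 in pair 5 after loess. In the brighter part of the probes the correlations lay between 0.13 and 0.62.

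**Figure D3:**
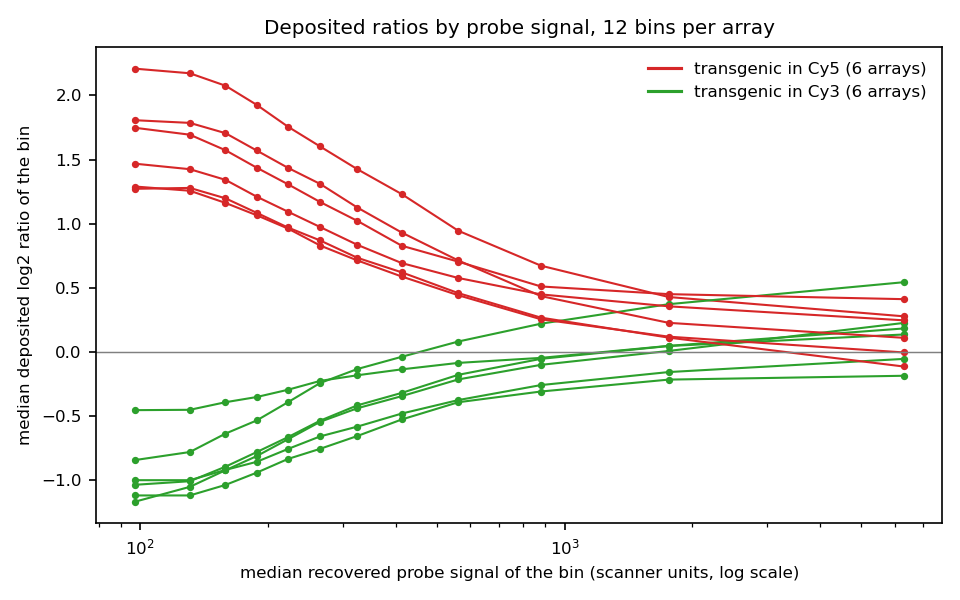
Median deposited log2 ratio (vertical axis) in 12 bins of recovered probe signal (horizontal axis, log scale, scanner units) for each of the 12 arrays. In the dimmest bin the medians lie from 1.27 to 2.21 with the transgenic sample in Cy5 and from -1.17 to -0.45 with it in Cy3, and in the brightest bin from -0.11 to 0.41 and from -0.19 to 0.54.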

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

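Of the tests in this part, only the comparison with random lists matched on signal and the splits of the pairs were chosen before their results were seen; the other tests were chosen after.

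3 lists had a pair far from the other 5. The hepatocyte median was 1.42 in pair 11, where the next highest was 0.26, the adipocyte median 1.04 in pair 15, where the next was -0.02, and the lymphocyte median -1.87 in pair 3, where the next was -0.15. The gaps took 0.814, 0.828 and 0.902 of the range, above Dixon's critical value for 6 values. Of 42 results tested in this way 2.1 would stand apart by chance.

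7 lists differed between the 2 groups in camera with the preset correlation. The 4-month minus 10-day medians were -0.43 for interferon response, -0.66 for macrophages, -0.69 for lymphocytes, -0.30 for ribosomal proteins, -0.58 for adipocytes, 0.15 for erythroid cells and -0.40 for hepatocytes. Without pair 3, interferon was at -0.23, macrophages at -0.36 and lymphocytes at -0.18, without pair 15, adipocytes at -0.08, ribosomal proteins at -0.18 and erythroid cells at 0.31, and without pair 11, hepatocytes at 0.13 and adipocytes at -0.87. Lymphocytes were at -1.04 without pair 1 and -1.03 without pair 5, erythroid cells at 0.07 without pair 13 and hepatocytes at -0.25 without pair 5. Of the 7 lists, interferon and macrophages alone passed without each pair in turn. None passed with an estimated correlation, where the lowest adjusted p was 0.683. The 10 splits of the 6 pairs into 3 and 3 are too few for a share under 0.05: 6 of them gave 7 lists or more, with 11 as the highest of the others. For genes, all 10 gave as many as the real 0, with 1 as the highest of the others.

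Chromaffin cell genes had positive ratios in all 6 pairs. A dye bias left after averaging is argued against by the separate dye orientations, whose mean list medians were 0.35 (SE 0.09) and 0.45 (SE 0.10), positive in 6 of 6 pairs each. A trend on signal is argued against by 10000 random lists of matched signal over all 6 pairs. Of these, 100% had a lower median (highest 0.16, against 0.29). A share of cortical cells that differs between the mice of a pair and moves all other cell types alike (lower in the transgenic mouse if the ratio is transgenic over wild type, higher if it is the inverse) would move the capsule and fibroblast list with the chromaffin list. The capsule list was positive in 1 of 6 pairs and lay below the chromaffin list by 0.51 ± 0.175 (SD, n = 6), which argues against such a shift for this list. The exact sign-flip p = 0.0312 of this difference is the smallest possible. It adds no support, because the chromaffin list was taken up for being positive in every pair. A different share of medulla in the mice of a pair would give the 27 chromaffin genes below the scanner limit a ratio of the same sign within each pair, and the share of positive genes ran from 59.3% in pair 11, where Gal was at 1.68 and Npy at 1.91 but Scg2 at -1.22, Gch1 at -0.95 and Dbh at -0.63, to 96.3% in pair 15. Such a share cannot be told apart from a change of some of these transcripts within chromaffin cells, because the marker lists measure composition only through transcripts, which a change of share and a change within the cells both move, and age, copy number and the direction of the ratio also stay open.

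Immune cell genes had negative ratios at 4 months, with the lowest medians in pair 3. For the lymphocyte list, lymphoid tissue in a sample of pair 3 is a candidate explanation: without this pair the median was -0.13 with adjusted p = 0.111, and in pair 3 Cd79b, Cd79a and Coro1a lay at -5.18, -4.18 and -3.94. The macrophage and interferon lists still passed camera with the preset correlation without pair 3, with adjusted p-values of 0.00667 and 4.68e-05 and medians of -0.35 and -0.25, against -0.60 and -0.49 with it, but not with an estimated correlation (0.804 and 0.716), and neither passed with the latter even with pair 3. For these lists such tissue cannot be told apart from a change in the other mice, because only pairs 1 and 5 are left, with medians of -0.07 and -0.47 for macrophages and -0.40 and -0.14 for interferon. Age and copy number stay open and were not tested apart.

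Nr5a1 had a negative ratio in 3 of 3 pairs at 10 days. A dye bias as the source of this sign is argued against by the 2 dye orientations, both negative (higher 10-day mean -0.63, SE 0.09). At 4 months the means were -0.50 with the transgenic sample in Cy5 and 0.13 with it in Cy3. A dye effect on the probe therefore stays open there. Nr5a1 did not pass at 10 days (limma adjusted p = 0.337), except under 1 of 24 alternatives, the deposited values with the all-gene median over all 6 pairs taken off, added after the data were seen (0.0297, range 0.0297 to 0.90). Under that alternative the median of all genes at 10 days was still -0.08. A ratio of wild type over transgenic cannot be told apart from a lower level in the transgenic mice, because neither the direction of the ratio nor the target of the probe is given in the sources used here. If the probe misses the transgene's transcript, its ratio says nothing of the transgene.

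Other splits were made by exchanging the sign of pairs. Over all 6 pairs, 1 of 32 splits, the real one, gave 12 genes, and the highest of the others gave 0. That is the smallest share this test can give, and the count fell to 0 without pair 13, 15, 1 or 3. The splits thus argue against chance for this count but do not exclude it. For lists over all 6 pairs, 30 of 32 splits gave 4 or more and the highest of the others gave 12, so chance cannot be excluded, and camera with the preset correlation calls lists whichever way the pairs are turned. At 10 days and at 4 months 4 splits are too few for a share under 0.05. The real counts of genes were 0 and 0, reached in 4 and 4 splits, with 0 and 1 as the highest of the others, and those of lists 3 and 6, reached in 4 and 2 splits, with 11 and 7 as the highest of the others.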

How the results depend on the processing

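The alternatives using deposited values, centred quantile values, turned columns, the dye difference of probes, a variance trend, the brighter features or probes, deviations, and pairs 11, 15 and 3 left out together were chosen after the data were seen; the cause of each change below was not tested unless stated.

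The counts are, in this order, genes changed at 10 days with 1 transgene copy, genes changed at 4 months with 2 transgene copies, genes changed over all 6 pairs, genes whose change differs between the 2 groups and genes whose change differs between the sexes, against 0, 0, 12, 0 and 0 in limma. Arrays of a single dye orientation gave 218, 915 and 3480 (Cy5 transgenic, 12 shared over all 6 pairs) and 30, 287 and 1441 (Cy3, 11 shared); a dye bias of single genes does not cancel there. All 12 arrays with the pair as a random block gave 69, 288, 767 (12 shared) and 18 for sex. The block correlation was 0.307, so this model treats the 2 arrays of a pair as largely independent, although they hold the same RNA. Quantile normalization gave 3825, 3340 and 11017, where the median of all genes was shifted by 0.27, 0.27 and 0.27, and 1 over all 6 pairs with that shift taken off. Values as deposited gave 18, 2548, 5964, 16 and 79, shifted by 0.20, 0.36 and 0.28, and 78, 118, 220, 16 and 79 with the all-gene median over all 6 pairs taken off. With that median off, a shift of -0.08 was left at 10 days and of 0.08 at 4 months. Columns turned gave 2504, 4764, 7277 (2 shared) and 1 for sex. Over all 6 pairs there were 0 genes with arrays centred, with arrays centred and scaled, with sex as a covariate, with a variance trend and without pairs 11, 15 and 3 together. There were 1 with the ordinary model (1 for sex), 7 with loess on the dye difference, 37 with the smaller dye disagreement (4 at 4 months) and 54 by probe. Leaving out each pair in turn gave 0 to 1, 0 to 2, 0 to 13, 0 to 0 and 0 to 3.

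Of the 12 genes, 11 were followed over all 6 pairs. All 241 values under the alternatives followed kept their sign and 103 stayed past the threshold, with adjusted p-values from 1.73e-05 to 0.278. These values include the fits on a single dye orientation and with the pair as a random block, which called far more genes. Single genes were not followed with quantile normalization, uncentred deposited values or turned columns, nor by probe.

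Lists passing at 10 days, 4 months, over all 6 pairs and for the difference were 3, 6, 4 and 7. With an estimated correlation they were 0, 0, 0 and 0, with fry 0, 0, 2 and 0. Centred arrays gave 5 at 10 days and 9 over all 6 pairs, Cy5 arrays 2 and Cy3 arrays 8 over all 6 pairs, and deposited values 9, 11 and 13. Leaving out pairs gave 3 to 6, 3 to 9, 2 to 8 and 5 to 7. The chromaffin list over all 6 pairs kept medians of 0.24 to 0.47 in 11 alternatives and passed in 10.

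Nr5a1 at 10 days was -0.94 (limma adjusted p = 0.0297) with deposited values and the all-gene median over all 6 pairs taken off, where the 10-day median of all genes was still -0.08. Over 24 alternatives the adjusted p of Nr5a1 ran from 0.0297 to 0.90, and leaving out pairs gave -0.71 to -0.61. At 4 months it was 0.13 on Cy3 arrays and -0.34 to -0.05 leaving out pairs. Agreement of the groups was -0.33 and -0.20 between opposite dye orientations and 0.18 to 0.35 leaving out pairs. The median dye-swap correlation was -0.39 with arrays centred, 0.48 for deviations and 0.45 for brighter probes.

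Of 2442 values of named genes other than Nr5a1 and of lists that had passed, 2074 kept direction and side of the threshold, 205 lost a call, 154 gained one and 9 reversed. On Cy5 arrays these were Amy2 0.0056, Ermap 0.050, Hspa8 -0.24 and Klf1 0.073, on Cy3 arrays Emcn 0.094, Lss 0.39, Prss2 0.027 and Zfy1 -0.23, and without pair 11 the hepatocyte difference 0.13 (-0.56 to 0.13 leaving out each pair). Lists that had not passed are outside this count: between the dye orientations, 8 of 27 lists had mean medians of opposite sign (gonadal-type genes 0.12 on Cy5 and -0.20 on Cy3 arrays, erythroid cells 0.12 and -0.27), and without pairs 11, 15 and 3 the medians of 6 lists turned, to 0.03 for cholesterol, 0.00 for cortical transcription factors, -0.06 for imprinted genes, -0.04 for kidney tubule cells, -0.08 for oxidative phosphorylation and -0.00 for Y-linked genes. Signal over background is unknown, and dim probes carry most of the dye trend.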

Other observations

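Apart from Cyp2f2, which the rule for named genes gave, the genes in this part were chosen after their values were seen. Their values by pair are given here without a further test; Pik3c2g is also among the genes called between the sexes without pair 15.

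The list of markers of the transient X-zone of the adrenal cortex had a median of -0.46 in pair 11 and between -0.11 and 0.10 in the other 5 pairs, while 3 of its genes had ratios far from 0 in single pairs. Akr1c18, a progesterone-degrading enzyme gene, was at -2.56 in pair 5 and -1.47 in pair 11, and between -0.27 and 0.56 in the other 4 pairs. Pik3c2g was at -5.77 in pair 5 and -1.92 in pair 11, and between -0.90 and 0.26 in the other 4 pairs. Cyp2f2 was at -4.21 in pair 15 and -1.75 in pair 11, and between -0.59 and 0.64 in the other 4 pairs. Of the steroidogenic genes, Cyp21a1, which encodes the steroid 21-hydroxylase, was at -3.18, -3.96 and 0.24 in pairs 11, 13 and 15 and at -1.41, 1.64 and 0.75 in pairs 1, 3 and 5. Star, which encodes the cholesterol carrier of the first step of steroid synthesis, was at 1.49 in pair 1 and -2.03 in pair 5, and Cyp11a1 at -1.01 in pair 11 and 1.14 in pair 1.

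Immediate early genes differed between pairs of the same group. The list median was -0.83 in pair 11 and -0.75 in pair 5, and 0.41 in pair 3. In pair 11 Nr4a1 was at -3.24 and Fos at -2.70, and Egr1 was at -1.49, while Egr1 was at 1.03 and 1.28 in pairs 13 and 15. Of genes that could show a difference in sex within a pair, Eif2s3y lay between -0.48 and 0.40 and Xist between -0.13 and 0.40 in all 6 pairs.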
